A study of Homo sapiens with 6 samples.

How the data were processed

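Total RNA of cells labelled Huh7 was sequenced after transfection with control siRNA or METTL3 siRNA, 3 libraries per group, per the labels. The groups and replicate numbers were taken from the sample titles. Libraries are named here by group and replicate number.

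The authors deposited 1 table per library with whole-number read counts per gene, not normalized. The submitters' processing notes name TopHat2 2.0.11, HTSeq and the genome build hg19 (GRCh37), without saying which step used which. The annotation release, the strandedness of counting and the treatment of reads with several alignments are not given in the sources used here. Each file lists 60483 Ensembl gene identifiers with versions. Symbols were taken from GENCODE 29 by identifier without version, which matched 56753 identifiers, and 3730 had no symbol. No line for unassigned reads was in the files (0). All 37 genes of the mitochondrial genome have 0 counts in every library, while a nuclear copy of mitochondrial sequence on chromosome 1, MTATP6P1, averaged 2352 CPM, so reads of mitochondrial origin cannot be read from these files by gene name. Without stated strand, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as HSPA1A and HSPA1B, are uncertain. Coordinates are given only for METTL3, from GENCODE 29 on GRCh38, and not from the build of the notes.

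Total counts per library were 12167403 to 25133887. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to 0.116 to 0.262 CPM, which covers counting error only. CPM values are counts scaled to the library total over tested genes (as in edgeR) after trimmed mean of M-values (TMM) normalization.

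Genes were kept by filterByExpr with its defaults (15390 of 30754 with any count). The main test was the edgeR 4.0.16 quasi-likelihood F test (glmQLFit and glmQLFTest, group only, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Figures were drawn with matplotlib 3.10.9.

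For gene lists, 40 lists were written before the data were examined, of pathways, cell type markers and signs of RNA quality. The 36 with at least 3 tested members were tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. No list passed the second way (0). Counts of called members are given over all genes tested and adjusted over the list alone. A further 10 lists were written after the first fit. They were 3 of heat shock factor targets, aminoacyl-tRNA synthetases and intestinal secretory and surface genes, and 7 of cell identity, for epithelium of intestine, stomach, lung, breast, prostate and kidney and for neural cells. The 8 of them with at least 3 tested members were tested and adjusted together.

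Genes are named by a rule set at the same time. It takes METTL3, then the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold with a mean of at least 5 CPM, a symbol and groups that do not overlap. It adds up to 4 called members of each list that passes or has at least 3 called members, every tested member of the m6A lists, and the 3 members with the highest mean CPM of each list of RNA quality or other cell types. Genes named outside this rule are marked as chosen after their values were seen, and so are the tissue genes given by level.

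Alternatives set at that time were DESeq2 size factors, library size only, no filter beyond 1 count, a filter at a mean of 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, a fold-change threshold, an adjusted p of 0.01, and each library left out in turn. Sample quality weights in limma-voom, and offsets per library for transcript length and GC content (natural splines with 5 degrees of freedom each, lengths known for 99.4% of tested genes), were added after the libraries had been seen.

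The procedure was tested on simulated counts with the means and library sizes of the real libraries and 200 changed genes. In the simulation of all 6 libraries (15180 genes), 2.99% of 1.5-fold, 52.2% of 2-fold and 95.5% of 4-fold changes were recovered, and 0.990% of the calls were false. In the simulation without METTL3 siRNA library 2 (15353 genes), the shares were 82.1%, 92.5% and 98.5%, and 5.21% of the calls were false. Each simulated gene had the same dispersion in all libraries. No simulated library stood apart, and there was no length trend and no correlation between genes. These rates therefore do not describe the real libraries, where METTL3 siRNA library 2 stood apart.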

Results

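The transcriptome of cells labelled Huh7, a line derived from a human hepatocellular carcinoma, was measured by RNA sequencing after transfection with a small interfering RNA against METTL3 or with a control siRNA. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on messenger RNA. Each of the 2 groups had 3 libraries. Gene counts summed to 14435643, 25133887 and 18631546 in control libraries 1, 2 and 3, and to 18554788, 12819426 and 12167403 in METTL3 siRNA libraries 1, 2 and 3. The labels do not say whether the libraries of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. Every pair of libraries in a group differed by more than sampling noise, with a mean chi-square per gene of 2.04 for the closest pair, METTL3 siRNA libraries 1 and 3, so all 6 were counted separately.

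METTL3 mRNA was lower in all 3 METTL3 siRNA libraries than in all 3 control libraries, but the difference missed the threshold of the test. The gene (ENSG00000165819.10) lies on the minus strand of chromosome 14 at 21498133 to 21511375 in GRCh38 with GENCODE 29 annotation. Its level was 56.0, 55.9 and 55.2 CPM in control libraries 1 to 3, and 46.8, 41.2 and 41.4 CPM in METTL3 siRNA libraries 1 to 3. The means were 55.7 ± 0.413 and 43.1 ± 3.19 CPM (SD, n = 3 each). The fitted ratio was 0.774, a log2 fold change of -0.37 with a standard error of 0.10, and the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.0567. Without METTL3 siRNA library 2 the same test gave -0.33 with an adjusted p of 6.01e-05. The DESeq2 Wald test on all 6 libraries gave -0.37 with an adjusted p of 0.0234.

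**Figure D1:**
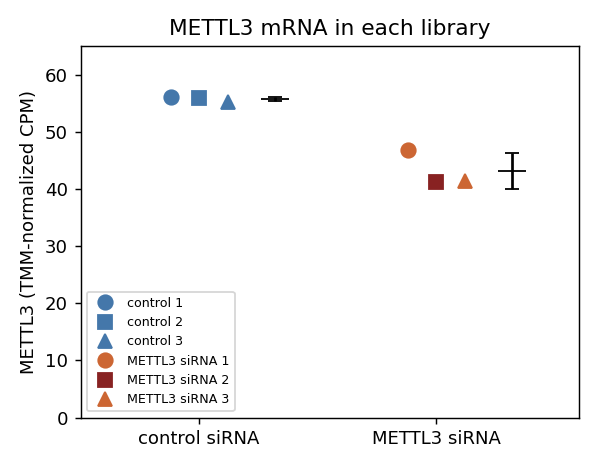
METTL3 level in TMM-normalized CPM (vertical axis, from 0) in each library of the control siRNA and METTL3 siRNA groups, with the mean and SD of each group (n = 3) to the right of its points. The METTL3 siRNA libraries lie between 41.2 and 46.8 CPM and the control libraries between 55.2 and 56.0 CPM.

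The question of the series was which genes METTL3 regulates in these cells. Of the 12 largest increases, 8 were in members of the integrated stress response list. NUPR1, a stress-induced chromatin-associated regulator, rose by 3.85 on the log2 scale (SE 0.34), from 7.95 ± 2.19 to 114 ± 45.3 CPM (SD, n = 3 each). ASNS, which makes asparagine, rose by 3.16 (SE 0.16), from 95.4 ± 6.27 to 852 ± 151 CPM. TRIB3, a pseudokinase induced under stress, rose by 3.04, CHAC1, which degrades glutathione, by 2.92, DDIT3, which encodes the transcription factor CHOP, by 2.71, and SLC7A11, the cystine transporter subunit, by 2.67. The other members of the 12 largest increases were PCK2 (2.56), ULBP1 (2.22), TSC22D3 (1.96), TAGLN (1.94), PSAT1 (1.72) and DDIT4 (1.70). Of these, PCK2 is the mitochondrial phosphoenolpyruvate carboxykinase, PSAT1 an enzyme of serine synthesis, ULBP1 a ligand of the receptor NKG2D, and DDIT4 an inhibitor of mTORC1 signalling.

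The 12 largest decreases were in genes of varied function. UCA1, a long noncoding RNA, fell by 3.84 on the log2 scale (SE 0.27), from 13.02 ± 2.65 to 0.927 ± 0.273 CPM (SD, n = 3 each). KRT20, an intestinal keratin, fell by 2.88 (SE 0.19), from 27.6 ± 0.543 to 3.68 ± 0.974 CPM, and MUC2, the secreted intestinal mucin, fell by 2.32 (SE 0.32), from 48.3 ± 3.20 to 9.60 ± 4.09 CPM. Of the heat shock proteins of the HSP70 family, HSPA1B fell by 2.34 and HSPA2 fell by 2.14. HSPA1A fell by 3.11, but HSPA1A and HSPA1B are near-identical copies between which reads can be divided, so each value alone is uncertain. The remaining members of the 12 largest decreases were AC131212.3 (-2.49), a transcript of chromosome 12 without an assigned gene class, MYH15 (-2.41), IFI6 (-2.03), an interferon-induced gene, HPCAL4 (-1.92), CEACAM6 (-1.89), a cell adhesion molecule, and NOS2 (-1.87), the inducible nitric oxide synthase.

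**Figure D2:**
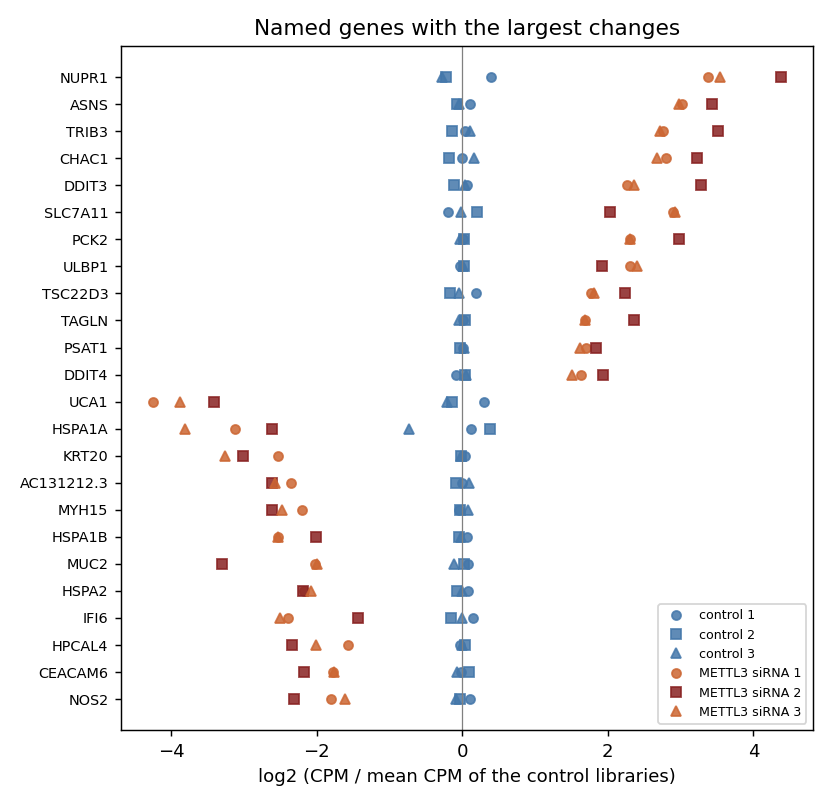
Log2 ratio of each library's CPM to the mean CPM of the control libraries (horizontal axis) for the 12 largest increases and 12 largest decreases among named genes, with a point for each of the 6 libraries. For all 24 genes the 3 METTL3 siRNA libraries lie on the same side of the 3 control libraries, from NUPR1 with a fitted log2 fold change of 3.85 to UCA1 with -3.84.

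In all, 2068 of 15390 tested genes passed a Benjamini-Hochberg adjusted p of 0.05 in the edgeR quasi-likelihood test, 1029 higher and 1039 lower after METTL3 siRNA. A change of at least 2-fold was fitted for 336 of the higher and 303 of the lower genes. The 2 groups did not overlap for any of the 2068 genes, and they did not overlap for 41.1% of all tested genes, where chance gives 10%. METTL3 siRNA library 2 stood apart, and without it 4351 genes were higher and 4472 lower, including all 2068. Without control library 1, 2 or 3 the test called 97, 89 and 93 genes, and without METTL3 siRNA library 1 or 3 it called 621 and 518. Of the 24 genes with the largest changes, 19, 19 and 20 stayed past the threshold without control library 1, 2 and 3, and all 24 did without each METTL3 siRNA library. Of all 88 called genes named by the rule, 28, 28 and 27 stayed past it without control library 1, 2 and 3, and 55, 88 and 52 without METTL3 siRNA library 1, 2 and 3. In all 6 of these fits 25 were called.

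METTL3 siRNA library 2 had the steepest trend along transcript length. Over 11193 genes with a mean of at least 5 CPM, its log2 ratio to the control mean correlated with transcript length at a Spearman coefficient of -0.57 across genes, which are not independent replicates. The coefficients were -0.413, 0.466 and -0.0292 in control libraries 1 to 3 and 0.190 and 0.185 in METTL3 siRNA libraries 1 and 3, where the trends were shallower. The 1121 genes with the shortest transcripts had a median log2 ratio of 0.64 in that library and the 1120 with the longest -0.65. The corresponding medians were -0.14 and 0.13 in METTL3 siRNA library 1 and -0.12 and 0.16 in library 3, and lay between -0.07 and 0.06 in the controls. Its log CPM correlated at 0.956 and 0.958 with the other METTL3 siRNA libraries, which correlated at 0.994 with each other.

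**Figure D3:**
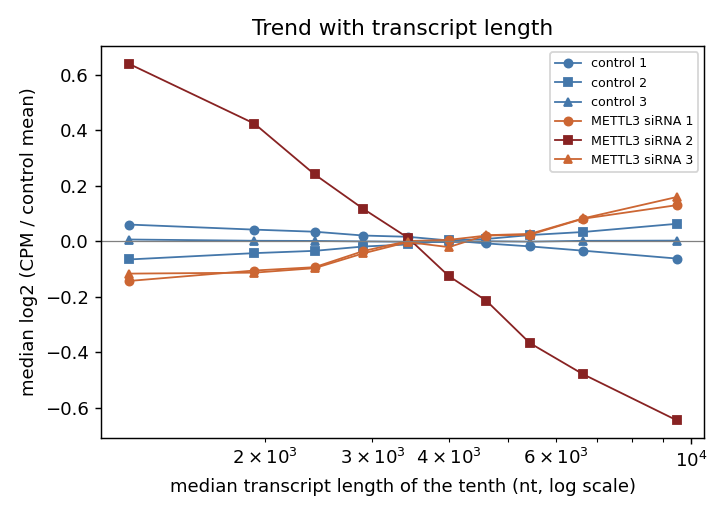
Median log2 ratio to the control mean (vertical axis) in 10 bins of genes ordered by transcript length (horizontal log axis, median length of each bin in nucleotides), with a line for each of the 6 libraries. METTL3 siRNA library 2 runs from 0.64 in the bin of shortest transcripts to -0.65 in that of the longest, while the other libraries stay between -0.14 and 0.16.

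Genes of the integrated stress response, the program run by the transcription factor ATF4, rose together. All 17 tested members of the list rose, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.70. The list passed the camera test at a Benjamini-Hochberg adjusted p of 8.67e-17, with an adjusted p = 0.457 with an estimated correlation. NUPR1, ASNS and TRIB3 led the list with FGF21, a secreted stress hormone that was measured at 0.0690, 0.116 and 0.106 CPM in the controls and at 1.05, 2.01 and 0.961 CPM after METTL3 siRNA. These control values were at or under the level of 3 counts (0.207, 0.116 and 0.158 CPM), so the size of its rise is uncertain. The FGF21 call was lost without control library 1, 2 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0634, 0.0701 and 0.0690). With METTL3 siRNA library 2 left out, the median was 1.49, and 17 of 18 tested members were called. The list of the unfolded protein response of the endoplasmic reticulum did not pass. HERPUD1 and DNAJB9, named after their values were seen, rose by 0.93 and 0.97, and the other 13 of 15 tested members were not called (3 higher and 1 lower adjusted over the list alone, camera adjusted p 0.953, Benjamini-Hochberg). When METTL3 siRNA library 2 was removed, 5 of the 15 were higher and 6 lower.

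Genes of DNA replication fell. Of 22 tested members, 13 fell and 9 were not called, with a median log2 fold change of -0.74, and 18 were lower adjusted over the list alone. Without METTL3 siRNA library 2, 20 were lower. The replicative helicase subunits MCM4, MCM3 and MCM6 fell by 1.06, 1.02 and 0.96, and GINS2, of the same helicase, fell by 0.97. The camera test gave a Benjamini-Hochberg adjusted p of 1.03e-08, with an adjusted p = 0.183 with an estimated correlation. Of the 22 mitosis genes none passed the edgeR quasi-likelihood test, adjusted over all genes or adjusted over the list alone (0 each, camera adjusted p 0.196, Benjamini-Hochberg). With METTL3 siRNA library 2 left out, 5 mitosis genes were higher and 11 lower.

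Interferon-stimulated genes fell. Of 19 tested members 7 fell, 0 rose and 12 were not called, with a median log2 fold change of -0.31, and 1 was higher and 8 lower adjusted over the list alone. IFI6 fell by 2.03, IFI27 fell by 1.80, and the oligoadenylate synthetases OAS3 and OAS1 fell by 1.001 and 0.72. The camera test gave a Benjamini-Hochberg adjusted p of 0.0157, with an adjusted p = 0.457 with an estimated correlation, and without METTL3 siRNA library 3 the adjusted p was 0.0528. When METTL3 siRNA library 2 was removed, 1 member was higher and 12 were lower.

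The hypoxia list was shifted upward. Of 15 tested members, VEGFA, a growth factor for blood vessels, rose by 1.59, NDRG1 by 1.30, P4HA1, a collagen prolyl hydroxylase, by 1.15, and BNIP3L, a mitophagy receptor, by 0.82. ERO1A, named after its value was seen, rose by 0.40 and the glucose transporter SLC2A1 fell by 0.76, leaving 9 not called. Adjusted over the list alone, 6 were higher and 2 lower, and without METTL3 siRNA library 2, 8 were higher and 2 lower over all genes. The camera test gave a Benjamini-Hochberg adjusted p of 0.0453, with an adjusted p = 0.513 with an estimated correlation. Leaving out METTL3 siRNA library 1, 2 or 3 or control library 3 ended that call, with adjusted p-values of 0.0654, 0.0610, 0.0719 and 0.0529 (camera, Benjamini-Hochberg). So did the replicate number as a block, with an adjusted p of 0.0610 (camera, Benjamini-Hochberg).

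Messenger RNAs of cytosolic ribosomal proteins, which are short, were higher as a list although 0 of 22 members passed the edgeR quasi-likelihood test, over all genes or adjusted over the list alone. Their median log2 fold change was 0.67, and it was 0.29 without METTL3 siRNA library 2, where 19 members were called higher. The median member was at 2657 CPM in METTL3 siRNA library 2, against 1342 and 1433 CPM in METTL3 siRNA libraries 1 and 3 and 1050 to 1179 CPM in the controls. The camera test gave a Benjamini-Hochberg adjusted p of 5.87e-05, with an adjusted p = 0.676 with an estimated correlation. These 5 lists were the ones that passed among 36 tested, and 0 passed with an estimated correlation.

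**Figure D4:**
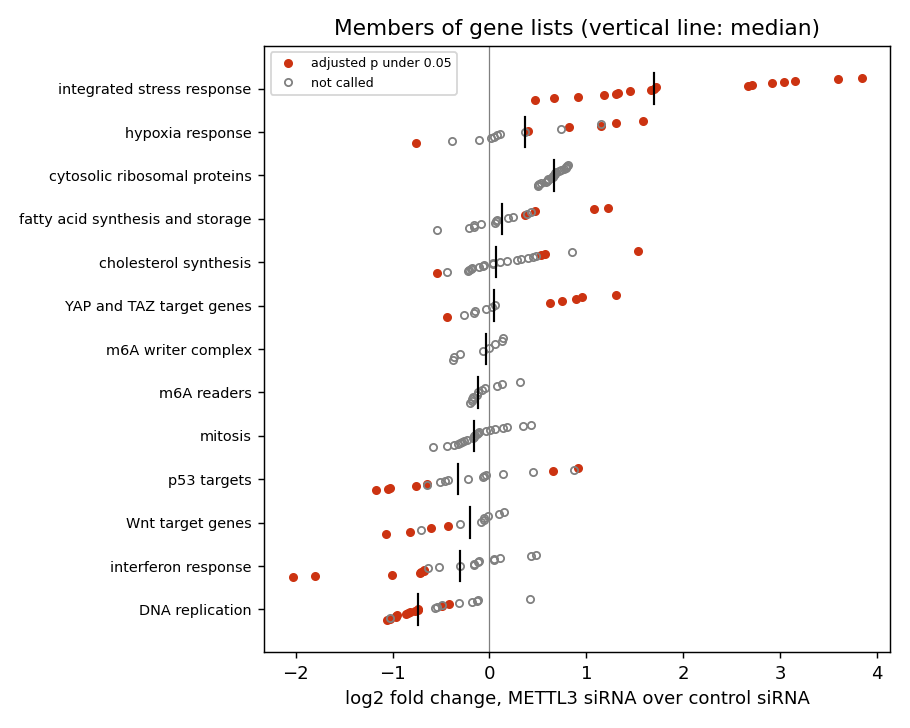
Log2 fold change of METTL3 siRNA over control siRNA (horizontal axis) for the tested members of 13 gene lists, with filled points for members past an adjusted p of 0.05, open points for the others and a vertical line at each median. The medians run from 1.70 for the integrated stress response to -0.74 for DNA replication.

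METTL3 missed the threshold, and the rest of the m6A machinery was mostly not called. None of the 8 members of the writer complex passed the edgeR quasi-likelihood test, over all genes or adjusted over the list alone. METTL14, the partner of METTL3, had a log2 fold change of -0.00 (SE 0.11), WTAP of 0.06 (SE 0.12), VIRMA of 0.14 (SE 0.18), RBM15 of -0.30 (SE 0.21), RBM15B of -0.07 (SE 0.09), ZC3H13 of -0.37 (SE 0.28) and CBLL1 of 0.13 (SE 0.19). FTO, an m6A demethylase, rose by 1.05 (SE 0.20), from 17.5 ± 1.42 to 36.1 ± 8.79 CPM (SD, n = 3 each). The cap methyltransferase PCIF1 rose by 0.51 and METTL16, another m6A methyltransferase, fell by 0.51. The FTO, PCIF1 and METTL16 calls were each lost without any library other than METTL3 siRNA library 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.0641 to 0.114, 0.0753 to 0.189 and 0.0858 to 0.195). ALKBH5 (-0.09), METTL5 (0.38) and ZCCHC4 (-0.12) were not called, which gave 2 higher and 1 lower of 6, also adjusted over the list alone. Of 11 tested m6A readers 0 were called, also adjusted over the list alone. Their log2 fold changes were -0.18 for YTHDF1, -0.18 for YTHDF2, -0.17 for YTHDF3, -0.13 for YTHDC1, -0.20 for YTHDC2, 0.31 for IGF2BP2, -0.05 for IGF2BP3, -0.08 for HNRNPA2B1, 0.08 for HNRNPC, -0.11 for FMR1 and 0.13 for EIF3A. Without METTL3 siRNA library 2, VIRMA (0.31) and CBLL1 (0.30) passed higher, as did the readers IGF2BP2 (0.50) and EIF3A (0.35), while ALKBH5 (-0.17), YTHDF1 (-0.18) and YTHDF2 (-0.22) passed lower. The camera adjusted p-values (Benjamini-Hochberg) of the writer, methyltransferase and eraser, and reader lists were 0.570, 0.579 and 0.570.

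Genes of lipid synthesis moved in both directions, and those named here rose. SREBF1 and SREBF2, which encode the transcription factors of fatty acid and cholesterol synthesis, rose by 1.23 and 0.54, and INSIG1, which restrains both, rose by 1.53. SCD, a fatty acid desaturase, rose by 1.08, ACSS2 by 0.47, ME1 by 0.36 and FDFT1 by 0.57. Of 16 tested genes of fatty acid synthesis and storage 4 rose and 12 were not called (4 higher adjusted over the list alone), and of 22 genes of cholesterol synthesis 3 rose (4 higher adjusted over the list alone). Neither list passed the camera test (Benjamini-Hochberg adjusted p 0.159 and 0.518), but with length and GC offsets the fatty acid list did, upward, with an adjusted p of 0.0333. Among 14 genes of fatty acid oxidation ANGPTL4, named after its value was seen, rose by 0.96 (2 higher adjusted over the list alone). In glycolysis the lactate transporter SLC16A3 fell by 0.999, SLC2A1 fell by 0.76 and PGAM1 fell by 0.50, and 13 of 16 were not called (1 higher and 4 lower adjusted over the list alone). None of 20 genes of oxidative phosphorylation was called, also adjusted over the list alone. The camera adjusted p-values (Benjamini-Hochberg) of these 3 lists were 0.478, 0.635 and 0.391. With METTL3 siRNA library 2 left out, 8 genes of fatty acid synthesis were higher and 2 lower, 8 of fatty acid oxidation higher and 2 lower, and 4 of glycolysis higher and 8 lower. For cholesterol synthesis 8 were then higher and 8 lower, and the median log2 fold change was -0.0317 in place of 0.0703. For oxidative phosphorylation the counts were then 2 higher and 9 lower, and the median log2 fold change was -0.15 in place of 0.21.

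Targets of p53 and cell cycle inhibitors moved in both directions. CDKN1A, which encodes the inhibitor p21, fell by 1.17, TIGAR fell by 1.05 and TP53INP1 fell by 1.02, and BTG2 and MDM2, named after their values were seen, fell by 0.76 and 0.64. SESN2, which is also in the stress response list, rose by 0.92 and GADD45A, named after its value was seen, by 0.65, leaving 11 of 18 p53 targets not called (4 higher and 7 lower adjusted over the list alone, camera adjusted p 0.147, Benjamini-Hochberg). CDKN1C and CDKN1B, which encode p57 and p27, rose by 1.49 and 0.86, and cyclin D3 (CCND3) fell by 1.19, with 4 of 8 members of that list not called (3 higher and 2 lower adjusted over the list alone, camera adjusted p 0.825, Benjamini-Hochberg). Among 16 apoptosis regulators PMAIP1 rose by 0.63 and BMF fell by 0.83, both named after their values were seen (1 higher and 2 lower adjusted over the list alone, camera adjusted p 0.642, Benjamini-Hochberg). None of 20 growth factor receptor and PI3K signalling genes was called, also adjusted over the list alone (camera adjusted p 0.570, Benjamini-Hochberg). When METTL3 siRNA library 2 was removed, 9 of these 20 were higher and 6 lower, as were 5 and 11 of the p53 targets, 3 and 5 of the cell cycle inhibitors and cyclins, and 5 and 7 of the apoptosis regulators.

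Signalling targets were also mixed. Among 12 Wnt targets LGR5, an intestinal stem cell receptor, fell by 1.06, TBX3 fell by 0.82, AXIN2 fell by 0.60 and TCF7 fell by 0.43 (5 lower adjusted over the list alone). Among 12 YAP and TAZ targets ANKRD1 rose by 1.31, AJUBA by 0.96, CTGF by 0.89, AMOTL2 by 0.75 and AXL by 0.63, and CYR61 (CCN1) fell by 0.44 (5 higher and 1 lower adjusted over the list alone). Among 19 immediate early genes ATF3, which is also a stress response gene, rose by 1.31, EGR1 by 0.89 and JUN by 0.65. Adjusted over the list alone, 3 were higher. The camera adjusted p-values (Benjamini-Hochberg) of these 3 lists were 0.0732, 0.172 and 0.0732. SOCS2, a negative regulator of cytokine signalling, rose by 0.89, from 44.0, 43.6 and 44.5 CPM in the controls to 82.5, 80.6 and 81.5 CPM, and 12 of 13 SOCS and STAT feedback genes were not called (1 higher adjusted over the list alone, camera adjusted p 0.478, Benjamini-Hochberg). Among 10 inflammatory cytokines and NF-kB targets LCN2 rose by 2.17 and CXCL3 fell by 1.13 (1 higher and 3 lower adjusted over the list alone, camera adjusted p 0.418, Benjamini-Hochberg). Without METTL3 siRNA library 2 the higher and lower counts were 0 and 6 for Wnt targets, 8 and 1 for YAP and TAZ targets, 8 and 4 for immediate early genes, 6 and 1 for SOCS and STAT genes and 2 and 5 for inflammatory genes. SOCS2, LCN2, CXCL3, AXL and CYR61 were named after their values were seen.

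Iron and redox genes included SLC7A11, which is also a stress response gene, and NFE2L2, which encodes NRF2 and rose by 0.72. The transferrin receptor TFRC and GCLM fell by 1.39 and 0.56. The other 13 of 17 were not called (2 higher and 2 lower adjusted over the list alone). Of the autophagy and lysosome genes ATG12 and ULK1 rose by 0.59 and 0.57, ATG16L1 fell by 0.71 and LAMP1 fell by 0.55, with 12 of 16 not called (2 higher and 2 lower adjusted over the list alone). In the methionine cycle MAT1A fell by 1.55, named after its value was seen, with 8 of 9 not called (1 lower adjusted over the list alone). Among mesenchymal genes TGFBI fell by 1.72, SPARC fell by 0.77 and SNAI1 fell by 0.71, with 9 of 12 not called (3 lower adjusted over the list alone). The camera adjusted p-values (Benjamini-Hochberg) of these 4 lists were 0.642, 0.893, 0.855 and 0.159. With METTL3 siRNA library 2 left out, they had 4, 3, 2 and 2 higher and 10, 4, 1 and 5 lower members.

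Most transcripts of hepatocyte secreted proteins were near 0 in the libraries, while several intestinal transcripts were abundant. ALB, among the most abundant transcripts of hepatocytes, had 4 counts over the 6 libraries and at most 0.116 CPM. AFP, which encodes alpha-fetoprotein, had 5 counts, TTR had 2, and APOB, FGA and FGB had 0, where 3 counts would be 0.116 to 0.262 CPM. The hepatocyte secreted proteins above 1 CPM on average were VTN at 73.1, SERPINA1 at 26.8, APOE at 7.97, APOH at 5.62, AMBP at 2.79, APOA2 at 1.75 and APOA1 at 1.64 CPM. The median over the 18 genes of that list was 0.252 to 0.697 CPM. For the 15 hepatocyte transcription factors it was 6.32 to 8.98 CPM. The median over 15 intestinal epithelium genes, a list written after the first fit, was 3.98 to 7.39 CPM, with VIL1 at 348, LGALS4 at 343, CDH17 at 286, CDX2 at 168 and CDX1 at 128 CPM on average. Other members were low, with GPA33 at 4.27, FABP1 at 3.03 and GUCY2C at 1.84 CPM, and OLFM4 had 0 counts. HNF4A, used in both tissues, was at 93.2 CPM. XBP1, which most cells use, also had 0 counts in every library, so a 0 in these files was not read as absence of a transcript.

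**Figure D5:**
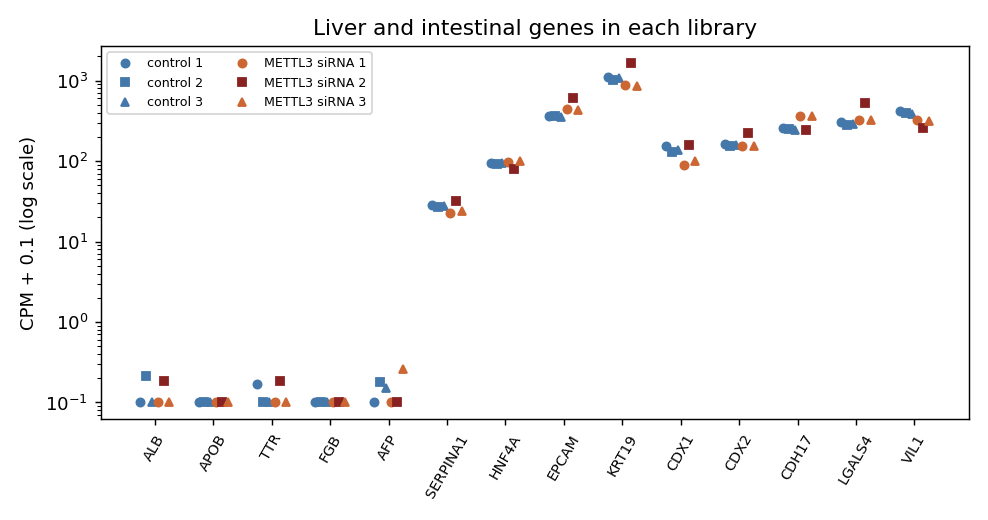
CPM plus 0.1 (vertical log axis) of 14 genes of liver, hepatoma and intestine in each of the 6 libraries. ALB reaches at most 0.116 CPM, while the means of CDX2 and CDH17 over the libraries are 168 and 286 CPM.

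Among the hepatocyte secreted proteins that were tested, APOA2 fell by 1.93, VTN fell by 1.48 and APOH fell by 0.94, and 5 of 8 were not called (3 lower adjusted over the list alone). Among 11 hepatocyte transcription factors CEBPB, which is also a stress response gene, rose by 1.18 and FOXA2 rose by 0.88, both named after their values were seen (3 higher adjusted over the list alone). None of 6 fetal liver and hepatoma markers was called (1 lower adjusted over the list alone), with H19 at 4802, KRT19 at 1103 and EPCAM at 429.5 CPM. Of 4 tested xenobiotic and bile acid enzymes CYP1A1 fell by 1.23, named after its value was seen (1 lower adjusted over the list alone). The camera adjusted p-values (Benjamini-Hochberg) of these 4 lists were 0.0924, 0.518, 0.825 and 0.501. When METTL3 siRNA library 2 was removed, they had 0, 5, 2 and 1 higher and 5, 2, 3 and 1 lower members. The acute phase list had 1 tested member, C3, named after its value was seen, which was not called (1 lower adjusted over the list alone), and no list test.

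Markers of other cell types and of RNA quality were low or mixed. Of the fibroblast and stromal markers COL5A1 fell by 1.46, COL1A1 fell by 1.44, ACTA2 fell by 0.71 and PDGFRB rose by 0.67, all at means under 12 CPM, and these were the 4 tested (1 higher and 3 lower adjusted over the list alone, camera adjusted p 0.0924, Benjamini-Hochberg). Leukocyte markers CD14, LYZ and CSF1R were at 4.26, 0.439 and 0.427 CPM, with 1 member tested and 0 called, also adjusted over the list alone. Endothelial markers ESAM, PECAM1 and VWF were at 12.1, 0.639 and 0.418 CPM, with 2 tested and 0 called (2 lower adjusted over the list alone). Of the squamous and keratin markers KRT80 fell by 0.82, at 16.6 CPM, and S100A2 and KRT81, at 5.90 and 1.31 CPM, were not called (1 lower of 4 adjusted over the list alone, camera adjusted p 0.642, Benjamini-Hochberg). Replication-dependent histone genes were at 5.94 CPM for HIST1H2BK, which fell by 1.07, 3.26 CPM for HIST1H1C and 1.87 CPM for HIST1H2BD, with 4 of 5 not called (2 lower adjusted over the list alone, camera adjusted p 0.0924, and 0.0333 with length and GC offsets, Benjamini-Hochberg). The list of nuclear-retained and of intron-rich noncoding RNAs had 7 tested members. GAS5 rose by 1.03 and SNHG1 by 0.65, both host genes of small nucleolar RNAs, and NEAT1 fell by 0.91 (2 higher and 1 lower adjusted over the list alone, camera adjusted p 0.527, Benjamini-Hochberg). GAS5 was at 458 CPM in METTL3 siRNA library 2 and at 245 and 247 CPM in METTL3 siRNA libraries 1 and 3, and its log2 fold change was 0.67 without library 2. Without METTL3 siRNA library 2, 3 histone genes, 1 leukocyte, 2 endothelial and 2 squamous markers were lower, and 5 of the noncoding RNAs were higher and 1 lower. The mitochondrially encoded mRNAs had 0 counts in all libraries and were not tested.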

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

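The sample quality weights and the length and GC offsets were tests chosen after the libraries had been seen. No called gene named by the rule changed sign in any alternative (0 of 1407 values for 88 genes), and no alternative gave a called gene among the 2068 the opposite sign where it was tested. The groups did not overlap for any called gene, so a change of sign was hardly possible. The stable signs are therefore no evidence that the calls hold under other processing. The counts of higher and lower genes stayed within 1.5 times 1029 and 1039 with DESeq2 size factors, library size only, both other filters, DESeq2 and limma-voom. They were 336 and 303 with an absolute log2 fold change of at least 1, 132 and 167 at an adjusted p of 0.01, 4426 and 4432 with sample quality weights, and 2265 and 2088 with length and GC offsets. Deviations from the group mean correlated at -0.263, -0.348 and -0.00289 between libraries of the same replicate number. In 0 pairs was the same number the best partner. METTL3 siRNA library 2 stood apart and weighs on every deviation of its group, so this check cannot tell whether the replicates were paired. With the replicate number as a block 7 and 8 genes passed. Leaving out each library in turn gave 34 to 4351 higher and 53 to 4472 lower genes, the highest without METTL3 siRNA library 2, whose removal lowered the biological coefficient of variation from 0.183 to 0.0378, and the lowest without a control library, for which the cause was not tested. METTL3 was -0.37 with DESeq2, -0.33 with quality weights and -0.44 with offsets, all past the threshold (adjusted p 0.0234, 0.000390 and 0.00582 by DESeq2, limma and edgeR, Benjamini-Hochberg), over a range of adjusted p from 6.01e-05 to 0.220, and -0.42 to -0.33 when a library was left out. In place of 5 passing lists among all those tested, 0 passed with an estimated correlation, 10 with no filter beyond 1 count, and 3 to 5 when a library was left out. The cause was not tested for the filter. Several m6A genes that were not called changed sign. METTL14 was 0.00274 with DESeq2 size factors, 0.00143 with no filter, 0.0716 with weights and 0.0467 with offsets. With weights WTAP was -0.0209, YTHDF3 0.0482, YTHDC1 0.00697, YTHDC2 0.0326, IGF2BP3 0.27, HNRNPC -0.0115 and FMR1 0.0404. With offsets RBM15B was 0.10 and HNRNPA2B1 0.0181. Leaving out a library gave -0.0353 to 0.0595 for METTL14, -0.0515 to 0.13 for WTAP, -0.31 to 0.0612 for YTHDF3, -0.33 to 0.0225 for YTHDC2, -0.34 to 0.28 for IGF2BP3, -0.0194 to 0.14 for HNRNPC, -0.24 to 0.0426 for FMR1 and -0.0101 to 0.35 for EIF3A. The cause was not tested. Depth limits genes under about 0.2 CPM, where 3 counts lie.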

Other observations

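The tests of the 10 added lists, and the tests of counting loss and of a mislabelled control, were chosen after the results were seen. Targets of the heat shock factor fell as a group after METTL3 siRNA. Of 18 tested members 12 fell, 0 rose and 6 were not called, with a median log2 fold change of -0.93. The constitutive chaperone HSPA8 fell by 1.23, from 4579, 4620 and 4656 CPM in the controls to 1853, 2210 and 1834 CPM. HSPH1 fell by 1.48, DNAJA1 fell by 1.49, CHORDC1 fell by 1.70, DNAJB1 fell by 1.09 and HSP90AA1 fell by 1.005. The camera test gave a Benjamini-Hochberg adjusted p of 2.29e-11 over the 8 lists added later, with an adjusted p = 0.0922 with an estimated correlation, and HSPA1A and HSPA1B had prompted the list. With METTL3 siRNA library 2 left out, all 18 were lower.

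Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, shifted upward as a list. Of 20 members 10 rose, 1 fell and 9 were not called (12 higher and 4 lower adjusted over the list alone), and without METTL3 siRNA library 2, 13 were higher and 7 lower. SARS rose by 1.34, CARS by 1.25, AARS by 1.22 and GARS by 1.003, while VARS fell by 0.55. Their camera adjusted p was 0.000706 (Benjamini-Hochberg), with an adjusted p = 0.209 with an estimated correlation. Of 14 intestinal secretory and surface genes, a list built partly from genes seen to fall and so not independent evidence of its direction, 8 fell and AGR2 rose by 1.17. REG4 fell by 1.70, GPX2 fell by 1.81, AQP3 fell by 1.68 and SPINK4 fell by 1.604. The camera adjusted p was 0.000706 (Benjamini-Hochberg), with an adjusted p = 0.0922 with an estimated correlation. In the intestinal epithelium list, which left those genes out, 3 of 13 fell, FABP1 by 1.70, CEACAM5 by 1.205 and GUCY2C by 2.06, and the list did not pass (camera adjusted p 0.113, Benjamini-Hochberg). When METTL3 siRNA library 2 was removed, that list had 4 higher and 7 lower members. The stomach, lung, prostate and neural lists did not pass either (camera adjusted p 0.785, 0.785, 0.112 and 0.785, Benjamini-Hochberg), and the breast and kidney lists had too few tested members.

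Why genes of intestinal epithelium were among the largest decreases in cells labelled as a liver line stays open. A small admixture of intestinal-type cells in a hepatocyte-like culture is argued against by ALB, which reached at most 0.116 CPM in any library, unless its reads were lost in counting. Such loss stays open, since 83.3% of the hepatocyte secreted protein genes had a count but several only a few reads, and XBP1 was at 0. A candidate explanation is that the libraries may come from cells of an intestinal epithelial type. The intestinal median was above that of the hepatocyte secreted proteins in 6 of 6 libraries. The medians of the stomach, lung, breast, prostate and kidney lists were at most 0.552 CPM. The intestinal median was, however, under that of the hepatocyte transcription factors in every library except control library 3. The lower bound of 5 CPM set for the intestinal median was met in control libraries 1 to 3, at 6.34, 5.78 and 7.39 CPM. It was also met in METTL3 siRNA library 2, at 7.32 CPM. METTL3 siRNA libraries 1 and 3 missed it, at 3.98 and 4.32 CPM. Members of this list fell after METTL3 siRNA, so the misses are not separate from the decreases to be explained. By the bound as set, for all 6 libraries, the explanation by cells of an intestinal epithelial type stays open.

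Why METTL3 siRNA library 2 stood apart is open too. Transcript length and GC bias could account for part of it, since offsets for both raised its lower correlation with the other METTL3 siRNA libraries from 0.956 to 0.970, but these still correlated at 0.994 with each other. A mislabelled control library is argued against by the slope of its changes on those of the other METTL3 siRNA libraries. That slope was 0.656 over the 8656 of 8823 genes called without library 2 that were also tested with it. Only 64.3% of these genes had the same sign (74.8% after the offsets). A slope near 0 was assumed for a control library but was not measured, and both sets of changes were taken against the same controls. A difference in the cells or their transfection was not tested.

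The rise of integrated stress response genes with the fall of heat shock genes was set against technical causes. Length and GC bias is argued against, as the median of the integrated stress response list was 1.64 after the offsets. Library 2 alone is argued against by a median of 1.49 without it. Both predictions were set for the integrated stress response list only. The heat shock list, prompted by genes seen to fall, had a median of -0.954 after the offsets and -1.05 without METTL3 siRNA library 2. Both responses may follow from METTL3 siRNA itself, from an effect of the siRNA on other targets or from differing medium conditions between the groups, which this design, with 1 METTL3 siRNA group, does not separate. The real grouping called 2068 genes and the highest of the other splits of the 6 libraries 0 (edgeR, with up to 1521 genes at an unadjusted p under 0.05), but 1 of 10 splits is the smallest share possible, too few for a share under 0.05.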
